A study of Mus musculus with 6 samples.

How the data were processed

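Immune cells sorted for CD45 from subcutaneous YUMM1.7 melanomas, a mouse melanoma line, were profiled by CITE-seq. This method counts the messenger RNAs of single cells together with antibody tags bound to their surface. The mice carried either a floxed Nr3c1 gene, which encodes the glucocorticoid receptor (floxed mice), or the floxed gene with a Cre recombinase driven by the Lyz2 promoter of myeloid cells (LysM-Cre mice). Each genotype received anti-PD-1 or an isotype control antibody, which made 4 conditions of 4 mice. Per the labels' protocols, 250000 tumour cells were injected into female mice aged 8 weeks, dosing with 12.5 mg/kg began at about day 7 and ran 2 times per week for 3 weeks, and tumours were taken at day 28. Cells of each mouse were tagged with a hashtag antibody before 8 mice were mixed into each of 2 pools, and each pool held 2 mice of every condition. Surface antibodies were added and cells sorted after mixing, and 25000 cells per pool were loaded onto 10x Genomics 3′ v3.1 reagents.

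The deposited values are unnormalized counts of unique molecular identifiers (UMIs) per feature and barcode. Per the file headers, Cell Ranger 6.1.2 wrote the matrices. The submitters' processing notes name Cell Ranger 3.0.1 and the mm10 build. The aligner settings are not given in the sources used here. Each matrix held 32285 genes, 8 hashtags and 88 surface antibodies, whereas 89 antibodies are stated in the labels' protocols. The rat IgG2a control had 0 counts in both pools. The condition of each hashtag was taken from the submitters' antibody table, in which 2 hashtags are printed with the same tag sequence. That table gives mice of one condition no numbers, so mice were numbered by pool and hashtag only to name them.

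Pool E5 held 15301 barcodes with 176338827 gene UMIs (median 8475 per barcode), and pool E6 held 16614 barcodes with 221763950 gene UMIs (median 8905). Barcodes were kept with at least 500 gene UMIs, at least 200 genes and at most 10% mitochondrial UMIs, which left 13914 and 14515. HTODemux (Seurat 5.3.0, positive quantile 0.99, within each pool) assigned 8065 and 8802 of them to 1 hashtag. It called 4209 and 4469 doublets of 2 hashtags and 1344 and 1242 negatives, which were left out. Doublets of 2 cells with the same hashtag remain, and their removal by Scrublet was an alternative setting.

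The 16867 cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, resolution 1.0). Nr3c1, the glucocorticoid response list, ribosomal, mitochondrial and antigen receptor genes were left out of the variable genes, and surface antibodies were not used. Clusters were named from fixed cell type markers where at least 3 were detected in at least 10% of cells with a mean log2 fold of at least 1.0. This scoring rule was set after the files were seen. Of 28 clusters, 22 were named in 13 classes, and 6 clusters with 1617 cells (9.59%) stayed unnamed because their leading genes went against the best name or their UMI counts were low.

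Gene counts were summed per mouse and class, for mice with at least 20 cells of the class and conditions with at least 3 such mice. The sums were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test) in one model of all conditions with the pool as covariate, and p-values were adjusted by Benjamini-Hochberg per contrast. The contrasts were genotype within each treatment, treatment within each genotype, and their interaction. Antibody counts with a total of at least 100 were tested the same way with TMM over the antibodies. Levels are given as CPM of the summed gene counts, or of the summed antibody counts (antibody CPM), and as mean ± SD over mice. A log2 change is written as LysM-Cre against floxed, or anti-PD-1 against isotype. Shares of cells were compared by exact two-sided permutation tests over mice, for which 4 against 4 mice cannot go below 0.0286, with Benjamini-Hochberg adjustment over 56 tests.

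Fixed gene lists were tested with camera in limma 3.58.1 at the preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move one way and compares them with no other genes. The 15 lists were glucocorticoid response, MHC class II presentation, interferon response, inflammatory cytokines, tissue-repair and tumour-associated macrophage, exhaustion, cytotoxic effector, naive and memory T, cell cycle, hypoxia and glycolysis, dissociation stress, and markers of melanoma cells, fibroblasts, endothelial cells and red cells. Lists with at least 3 tested members entered the set test, and members were also adjusted over the list alone.

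Genes named as changed passed adjusted p 0.05 over all genes at an average of at least 10 CPM with the fitted sign in at least 3/4 of the mice, leaving out unnamed models. Exceptions, named after their values were seen, were Cd3g, Cd24a, Lyz1, Lyz2, Cd163, Hspa1a and Hspa1b. Nr3c1 was given in every class, and list members are named to show a list's range. Conditions, markers, lists, tests and most alternatives were fixed before the data were examined. The alternatives were another hashtag rule (top hashtag with at least 10 counts and 70% of the barcode's hashtag counts), at most 20% mitochondrial UMIs, resolutions 0.5 and 2.0, Scrublet, DESeq2 1.42.0, no filter on low counts, at least 50 cells, no pool term, centred log ratios with limma, no isotype control antibodies, and each mouse left out in turn. Contrasts over both treatments or both genotypes, a merged macrophage and monocyte class, and antibody fits without 2 barcodes of aggregated antibody were added after seeing the data.

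The edgeR fit was tested on simulated data with known changes for treatment in floxed mice. In macrophages, 58 of 100 genes changed by 1 on the log2 scale and 95 of 100 changed by 2 were called among 9568 genes, and 10 of 9368 unchanged genes were called. In CD8 T cells 50 of 98 and 88 of 98 were called among 5841 genes. Counting intervals are not given for summed counts, whose error is the spread between mice.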

Results

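Messenger RNA and 88 surface antibodies were counted in single CD45-sorted cells from melanomas of 16 mice, 4 in each combination of genotype (floxed or LysM-Cre) and antibody (isotype or anti-PD-1). The 16867 cells assigned to 1 mouse ranged from 133 in floxed anti-PD-1 mouse 2 to 3083 in floxed isotype mouse 3, and gene UMIs per mouse from 1610059 to 29402226. Floxed isotype mice gave 1795.5 ± 941 cells (SD, n = 4) and LysM-Cre isotype mice 1305.5 ± 729, whereas anti-PD-1 gave 504.5 ± 284 in floxed and 611 ± 194 in LysM-Cre mice. Exact two-sided permutation tests of anti-PD-1 against isotype gave p = 0.0286 in floxed mice (adjusted 0.114) and p = 0.0857 in LysM-Cre mice (adjusted 0.171), so neither difference passed after adjustment. Between genotypes the exact p was 0.429 with isotype and 0.543 with anti-PD-1. The numbers also depend on how the cells of 8 mice were mixed before sorting.

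Monocyte-like cells were the largest class with 5478 cells (32.5%), followed by macrophage-like (2157), neutrophil-like (1679), CD8 T-like (1564) and NK-like cells (1122). Fibroblast-like (975), regulatory T-like (744), CD4 T-like (525), cDC2-like (510), mast or basophil-like (209), mature DC-like (108), B-like (98) and pDC-like cells (81) were fewer. These classes were named from markers, and the suffix is left out in what follows. A sort for CD45 should remove fibroblasts, yet 975 cells carried their markers. Unnamed clusters held 10.9 ± 2.00% of the cells in floxed isotype mice, 11.8 ± 3.82% in LysM-Cre isotype, 7.09 ± 1.43% in floxed anti-PD-1 and 6.95 ± 4.25% in LysM-Cre anti-PD-1 mice. Summed gene UMIs per mouse ranged from 556815 to 6189843 in macrophages and from 314104 to 14810750 in monocytes. The genes tested ranged from 10116 in fibroblasts and 9579 in macrophages to 2140 in neutrophils.

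The first comparison asks whether the targeted gene was lower where Cre is active. Nr3c1 (chromosome 18, 39410545 to 39519421, mm10) had lower mean levels in LysM-Cre than in floxed macrophages and monocytes. Tested alone it passed p 0.05, but not over all genes. Macrophages of floxed isotype mice 1 to 4 had 85.1, 58.1, 47.4 and 80.7 CPM, and floxed anti-PD-1 mice 63.4, 53.9, 56.0 and 52.55 CPM. LysM-Cre isotype mice had 36.05, 24.5, 41.1 and 75.55 CPM, and LysM-Cre anti-PD-1 mice 22.9, 23.75, 28.4 and 39.4 CPM. In monocytes the floxed mice lay between 52.5 and 70.3 CPM. LysM-Cre isotype mice 1 to 4 had 52.7, 35.1, 38.9 and 60.4 CPM, and LysM-Cre anti-PD-1 mice 30.4, 24.85, 37.7 and 37.45 CPM. The log2 change by genotype in monocytes was -0.46 with isotype (edgeR adjusted p = 0.9999) and -0.96 with anti-PD-1 (adjusted p = 0.0698, all 4 LysM-Cre mice below all floxed mice). In macrophages it was -0.60 (adjusted p = 0.9999) and -1.03 (adjusted p = 0.303). Each of the 4 passed at unadjusted p 0.05. The anti-PD-1 change passed over all genes in monocytes with DESeq2 (adjusted p = 0.00102), without a filter on low counts (8.74e-06) and without LysM-Cre isotype mouse 4 (0.0413), and in macrophages without a filter (6.62e-05). Without LysM-Cre isotype mouse 2 or 4 the isotype change in macrophages was -0.35 and -1.01.

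Neutrophils, in which the Lyz2 promoter is also active, had 153 ± 81.4 CPM of Nr3c1 in floxed isotype, 83.0 ± 32.0 in LysM-Cre isotype and 80.6 CPM in LysM-Cre anti-PD-1 mice (genotype with isotype -0.86, edgeR adjusted p = 0.999). In CD8 T cells the 4 conditions had means of 101, 100, 95.9 and 102 CPM in the order floxed isotype, LysM-Cre isotype, floxed anti-PD-1 and LysM-Cre anti-PD-1. NK cells had 73.2, 58.0, 80.1 and 78.5 CPM and fibroblasts 86.5, 84.2, 84.5 and 96.4 CPM in that order. With isotype, CD4 T cells had 262 CPM in floxed and 236 in LysM-Cre mice, regulatory T cells 150 and 186, and cDC2 cells 49.8 and 35.9. Reads come from the 3′ ends of transcripts and the labels do not say which exons are removed, so these levels do not check the deletion.

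**Figure D1:**
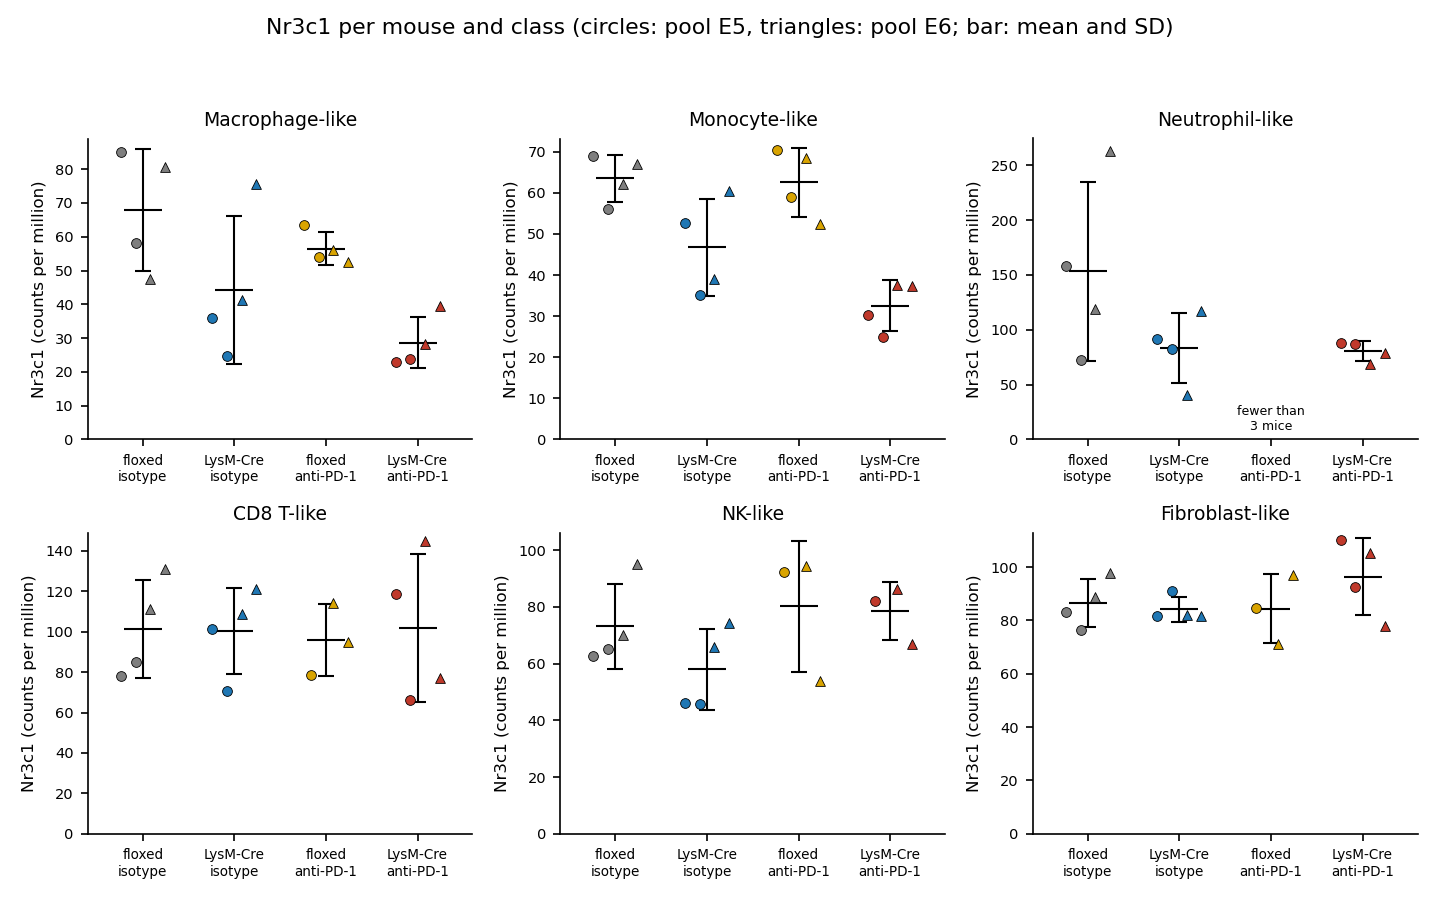
Nr3c1 level in CPM (vertical axis, linear from 0) per mouse in 6 classes for the 4 conditions, with points for mice (circles for pool E5, triangles for pool E6) and bars for mean and SD. In monocytes the 4 LysM-Cre anti-PD-1 mice lie between 24.85 and 37.7 CPM and the floxed mice between 52.5 and 70.3 CPM.

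Shares of cell classes addressed which immune cells filled the tumours. CD8 T cells made up 11.05 ± 3.599% of cells in floxed isotype and 5.56 ± 1.87% in floxed anti-PD-1 mice. Regulatory T cells made up 5.18 ± 1.22% and 1.56 ± 0.653%, and mature DCs 1.004 ± 0.624% and 0.198 ± 0.141%. With anti-PD-1, mast cells and basophils made up 2.15 ± 1.37% of cells in floxed and 0.388 ± 0.163% in LysM-Cre mice. In these 4 comparisons the groups did not overlap, and the exact p was 0.0286, the smallest that 4 against 4 mice allow, or 0.0556 where mice were relabelled within pool. None of the 56 tests passed after adjustment (smallest 0.40), which that floor all but precluded. Macrophages made up 9.73 ± 3.05% of cells in floxed isotype, 16.3 ± 10.05% in LysM-Cre isotype, 20.8 ± 13.7% in floxed anti-PD-1 and 18.5 ± 14.8% in LysM-Cre anti-PD-1 mice. Monocytes made up 29.6 ± 9.66%, 24.1 ± 14.3%, 36.7 ± 16.9% and 34.0 ± 9.53% in that order. The CD45 sort sets all of these denominators.

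**Figure D2:**
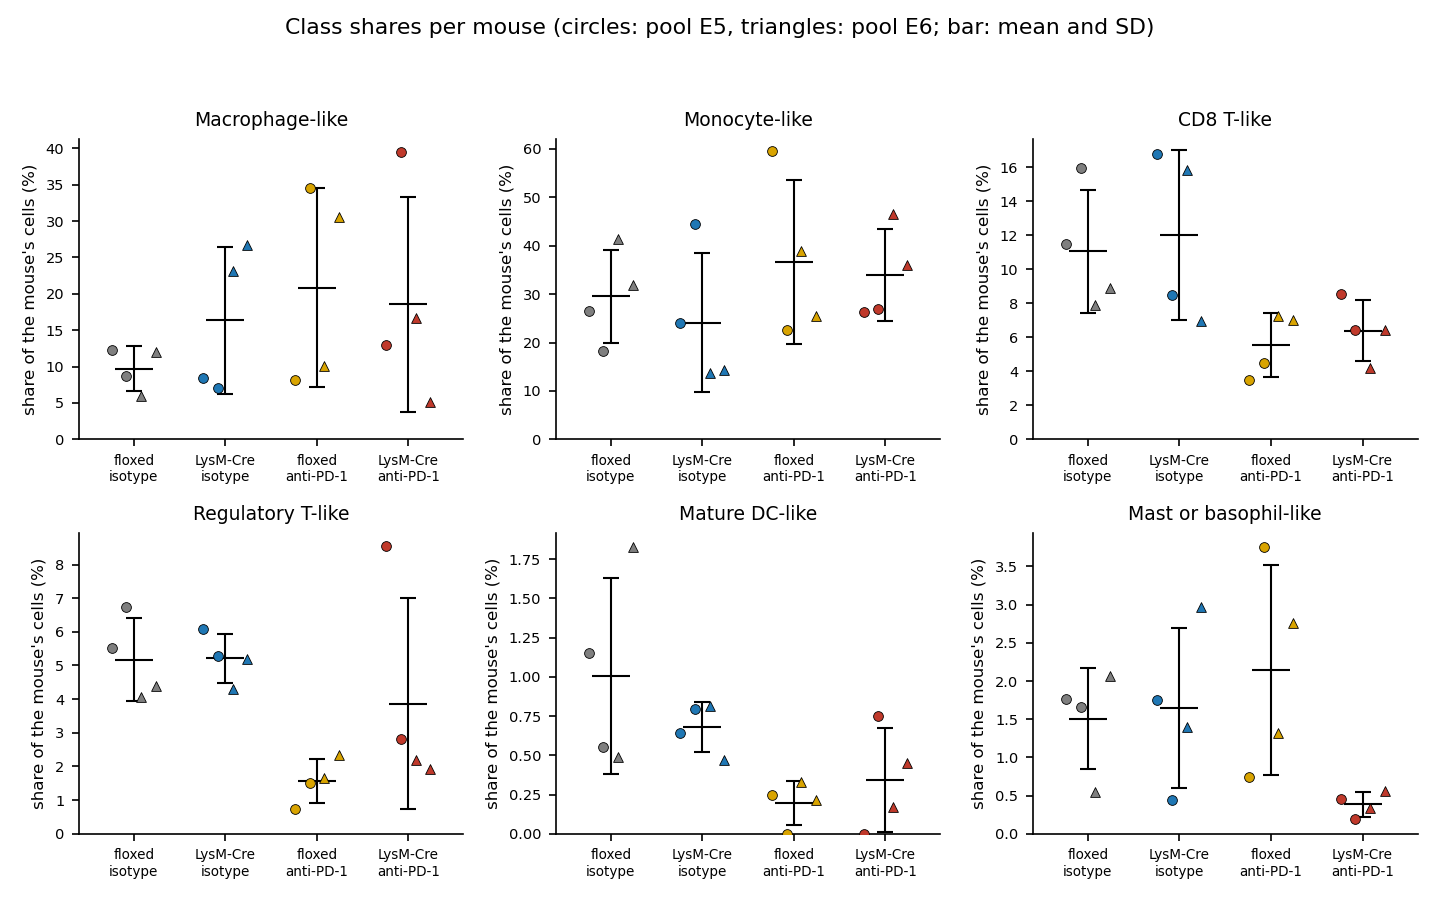
Percent of a mouse's analysed cells in 6 classes (vertical axes, linear from 0) for the 4 conditions, with points for mice (circles for pool E5, triangles for pool E6) and bars for mean and SD. Mast cells and basophils average 2.15% in floxed and 0.388% in LysM-Cre mice with anti-PD-1.

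In macrophages of floxed mice, interferon-response genes were lower with anti-PD-1 than with isotype as a group, and antigen-presentation genes of MHC class II were lower with them. All 27 measured interferon genes had lower fitted levels, with a median log2 change of -1.31 (-0.80 with the other hashtag rule), and 13 of them passed when adjusted over the list alone. Bst2, a restriction factor that tethers virus particles, was at 517 ± 93.5 CPM with isotype and 303 ± 61.2 CPM with anti-PD-1 (SD, n = 4 each). Irf7, a transcription factor that amplifies interferon production, was at 195 ± 65.1 and 40.5 ± 22.6 CPM, and Zbp1, a sensor of viral nucleic acid, at 120 ± 36.4 and 43.8 ± 18.6 CPM. All 10 MHC class II genes were lower (median -0.67), and 1 of them, H2-Oa, passed when adjusted over the list alone (12.6 to 1.49 CPM). Camera gave adjusted p = 4.1e-24 for the interferon list and 7.92e-05 for the MHC class II list, against adjusted p = 0.173 and 0.428 with an estimated correlation. I-A/I-E, the MHC class II surface protein, had a log2 change of 0.0348 (adjusted p = 0.981).

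Genes of lymphocytes were also lower in these macrophages, and the sum of 12 T and NK cell markers went from 77.5 ± 64.8 (171 in floxed isotype mouse 2) to 10.4 ± 5.96 CPM. The cytotoxic effector list fell (3 of 4 genes down, median -2.42, camera adjusted p = 0.000272, adjusted p = 0.092 with an estimated correlation), and Klrd1, Nkg7 and Ccl5 passed when adjusted over the list alone. Cd3g, a subunit of the T cell receptor complex, fell by 3.28 on the log2 scale (13.6 ± 6.39 to 1.47 CPM, edgeR adjusted p = 0.0279) and Cd24a, a surface glycoprotein, from 14.7 ± 6.34 to 0.50 CPM (-4.62, adjusted p = 0.0279, and -1.47 with the other hashtag rule), and no other gene of 9579 passed. Red cell markers were at 1403 ± 2395 CPM with isotype, where 1 mouse had 4988 CPM, and at 40.9 ± 34.6 CPM with anti-PD-1. CD169, a sialic-acid receptor of macrophages, fell as the 1 of 87 surface proteins past adjusted p 0.05 (1039 ± 96.4 to 494 ± 145 antibody CPM, -1.08, adjusted p = 0.0485). At unadjusted p 0.05 the counts were 1229 genes and 14 proteins, and DESeq2 called 117 genes. Over both genotypes 13 genes and 21 proteins (14 lower) passed for treatment. The 2 gene calls depended on single mice: the count was 0 without floxed isotype mouse 1 or 2 or floxed anti-PD-1 mouse 3 or 4, 1 without floxed anti-PD-1 mouse 2, 8 without LysM-Cre anti-PD-1 mouse 4, 14 without LysM-Cre isotype mouse 3, 22 without floxed isotype mouse 4, and 31 without LysM-Cre isotype mouse 2 or 4. Cd3g was also lost without floxed isotype mouse 3 or floxed anti-PD-1 mouse 1 (adjusted p up to 0.172). CD169 was lost in 7 of 16 fits without 1 mouse (adjusted p 0.0521 to 0.196).

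With anti-PD-1, LysM-Cre macrophages had higher interferon and MHC class II levels than floxed macrophages, and lower cell cycle levels. All 27 interferon genes were higher (median 1.12, camera adjusted p = 4.33e-16, adjusted p = 0.431 with an estimated correlation), among them Irf7 (40.5 ± 22.6 to 159 ± 82.4 CPM) and Cxcl9, a chemokine that draws T cells (159 to 613 CPM). All 10 MHC class II genes were higher (median 0.75, adjusted p = 6.26e-06, adjusted p = 0.431 with an estimated correlation), such as H2-Aa at 1618 ± 628 and 3659 ± 1438 CPM and Cd74, the invariant chain, at 4792 and 9411 CPM. All 14 cell cycle genes were lower (median -0.49, adjusted p = 4.7e-05, adjusted p = 0.544 with an estimated correlation). No member of these lists passed when adjusted over the list alone, whereas Ccl5, a chemokine of the cytotoxic list, did (40.5 to 296 CPM, 2.80). Glucocorticoid-response genes did not pass as a list (14 of 22 up, adjusted p = 0.476, adjusted p = 0.855 with an estimated correlation). EdgeR called 0 genes past adjusted p 0.05 over all genes (1075 at unadjusted p 0.05, 22 by DESeq2) and 0 surface proteins (6 at unadjusted p 0.05). The gene count was 2 without LysM-Cre anti-PD-1 mouse 1, 1 without LysM-Cre isotype mouse 3 and 4 without LysM-Cre isotype mouse 4. Without floxed anti-PD-1 mouse 3 the interferon median was 1.68 and the cell cycle median -0.29.

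The interaction asks whether the response to anti-PD-1 differed between genotypes. In macrophages 26 of 27 interferon genes had a higher response in LysM-Cre mice (median 1.26, camera adjusted p = 1.93e-19, adjusted p = 0.549 with an estimated correlation), and without LysM-Cre isotype mouse 2 the median was 2.26. All 10 MHC class II genes did so (median 0.69, adjusted p = 0.00234, adjusted p = 0.724 with an estimated correlation), which was lost without floxed isotype mouse 2 (adjusted p = 0.0825) or LysM-Cre isotype mouse 4 (adjusted p = 0.0508), and I-A/I-E protein had -0.0569 (adjusted p = 0.99). EdgeR and DESeq2 each called 0 genes (586 at unadjusted p 0.05 in edgeR), and 0 proteins passed (2 at unadjusted p 0.05).

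**Figure D3:**
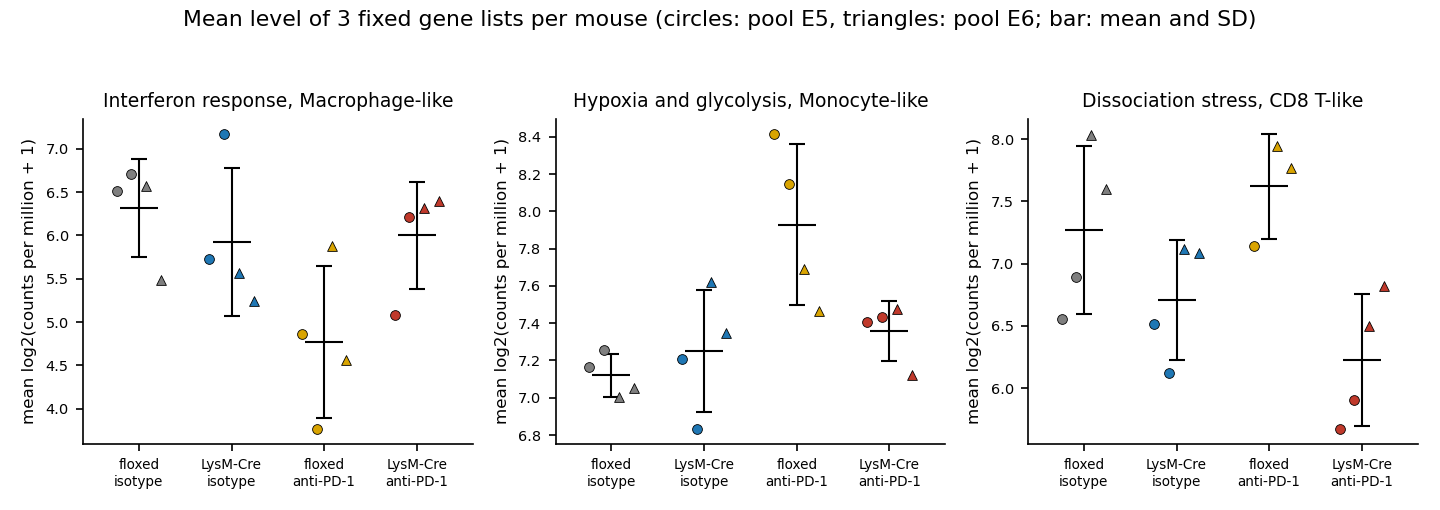
Mean level of 3 gene lists per mouse, as log2(CPM + 1) averaged over list members (vertical axes, which do not start at 0), for interferon genes in macrophages, hypoxia genes in monocytes and stress genes in CD8 T cells, with points for mice (circles for pool E5, triangles for pool E6) and bars for mean and SD. The interferon mean is 6.32 ± 0.56 in floxed isotype and 4.77 ± 0.87 in floxed anti-PD-1 mice.

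With isotype, LysM-Cre and floxed macrophages differed in no gene by edgeR or DESeq2 (269 at unadjusted p 0.05 in edgeR) and in 0 proteins (2 at unadjusted p 0.05). Interferon (22 of 27 down, median -0.23, camera adjusted p = 0.00768), cell cycle (13 of 14 down, -0.22, adjusted p = 0.0281) and hypoxia genes (9 of 12 down, -0.14, adjusted p = 0.00815) had adjusted p = 0.639, 0.639 and 0.592 with an estimated correlation. Without floxed isotype mouse 2 none of the 3 calls held (adjusted p 0.29 to 0.35 for the latter 2), and each was lost without 2 or more other mice (adjusted p up to 0.807). Medians ranged from -0.85 (without LysM-Cre isotype mouse 2) to 0.0040 (mouse 4) for interferon, -0.50 (mouse 3) to 0.0268 (mouse 4) for hypoxia and -0.35 (mouse 4) to -0.0057 (mouse 3) for cell cycle genes. Glucocorticoid-response genes went both ways (9 up and 13 down, adjusted p = 0.346).

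In LysM-Cre macrophages, hypoxia and glycolysis genes were higher with anti-PD-1 (11 of 12, median 0.42, camera adjusted p = 4.86e-05, adjusted p = 0.387 with an estimated correlation). Ndrg1, a gene induced by low oxygen, was at 14.6 CPM with isotype and 30.45 CPM with anti-PD-1. The call was lost without LysM-Cre isotype mouse 4 (adjusted p = 0.0637), and the median was 0.26 without LysM-Cre anti-PD-1 mouse 4. The cytotoxic list had a median of -1.03 (2 of 4 genes down, adjusted p = 0.0285, adjusted p = 0.297 with an estimated correlation), and Klrd1 (11.55 to 2.13 CPM) and Nkg7 (9.39 to 1.87 CPM) passed when adjusted over the list alone. The list was lost without LysM-Cre anti-PD-1 mouse 1 (adjusted p = 0.169), and its median ranged from -2.62 to -0.99 over the fits without 1 mouse. The 3 tested fibroblast markers fell (median -0.70, adjusted p = 0.00588, adjusted p = 0.254 with an estimated correlation), lost without LysM-Cre isotype mouse 1 (adjusted p = 0.0701). EdgeR called 0 genes (453 at unadjusted p 0.05, 3 by DESeq2, 1 in edgeR without LysM-Cre isotype mouse 2) and 0 proteins (22 at unadjusted p 0.05, 2 without LysM-Cre isotype mouse 3). CX3CR1, the fractalkine receptor, had a protein change of -0.78 (adjusted p = 0.0965).

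Monocytes of floxed mice had higher hypoxia, inflammatory and exhaustion-list levels with anti-PD-1 than with isotype. All 12 hypoxia and glycolysis genes were higher (median 0.65, camera adjusted p = 5.73e-15, adjusted p = 0.0535 with an estimated correlation), and 11 passed when adjusted over the list alone. Ndrg1 went from 46.6 ± 5.11 to 183 ± 96.8 CPM, and Hilpda, a lipid-droplet protein induced by low oxygen, from 46.1 ± 13.2 to 170.5 ± 66.2 CPM. All 16 inflammatory genes were higher (median 0.66, adjusted p = 1.44e-08, adjusted p = 0.114 with an estimated correlation), with Ptgs2, the inducible cyclooxygenase (71.4 ± 34.6 to 215 ± 85.1 CPM), and Clec4e, a lectin receptor (140 ± 42.9 to 319.6 ± 107 CPM), past the threshold when adjusted over the list alone. All 5 exhaustion genes were higher (median 0.54, adjusted p = 0.00436, adjusted p = 0.0535 with an estimated correlation), of which Cd244a passed over the list alone. Stress genes (11 of 12, median 0.28, adjusted p = 0.00642, adjusted p = 0.297 with an estimated correlation) and glucocorticoid-response genes were also higher as lists (the latter 16 of 23, median 0.27, adjusted p = 0.00142, adjusted p = 0.297 with an estimated correlation). Of the latter Mt1 and Mt2, which encode metal-binding metallothioneins, rose when adjusted over the list alone (Mt1 292.5 ± 155 to 659.5 ± 228 CPM), whereas Txnip, an inhibitor of thioredoxin, fell (304 ± 29.3 to 208 ± 30.4 CPM). Cluster 14 of this class, led by Slpi, Cxcl3 and Inhba, held 3.82 ± 2.8% of monocytes in floxed isotype and 24.3 ± 18.1% in floxed anti-PD-1 mice. Without floxed isotype mouse 2 the inflammatory median was 0.39 and the glucocorticoid median 0.17, and without floxed anti-PD-1 mouse 1 the latter was 0.14 and the stress call was lost (adjusted p = 0.0519). The stress median was 0.17 without floxed anti-PD-1 mouse 3.

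Interferon genes of floxed monocytes were lower with anti-PD-1 in 20 of 27 cases (median -0.32, camera adjusted p = 0.000464, adjusted p = 0.605 with an estimated correlation). This rested on floxed anti-PD-1 mouse 2, without which the median was -0.0045 (adjusted p = 0.962), and it was -0.19, -0.16 and -0.62 without floxed isotype mouse 1, floxed anti-PD-1 mouse 1 and floxed anti-PD-1 mouse 3.

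EdgeR called 3 of 9476 genes in floxed monocytes, all higher with anti-PD-1 (adjusted p = 0.0233 each). Prdm1, a transcriptional repressor (chromosome 10, 44437174 to 44528558, mm10), rose from 38.9 ± 4.09 to 79.1 ± 12.1 CPM, Card19, a CARD-domain protein, from 129 ± 15.6 to 215 ± 27.3 CPM, and Snapc1, a subunit of the small nuclear RNA activating complex, by 0.95 on the log2 scale. At unadjusted p 0.05 there were 1115 genes. The count was 0 without floxed isotype mouse 1, 2 or 4 or floxed anti-PD-1 mouse 1 or 3, 1 without floxed anti-PD-1 mouse 2, and 28 without floxed anti-PD-1 mouse 4. Without floxed isotype mouse 3, Snapc1 and Card19 were lost and Prdm1 was not, and lost adjusted p-values ranged from 0.0512 to 0.303. Surface proteins past the threshold numbered 4 of 87. CD169 fell from 433.5 ± 69.5 to 151 ± 22.1 antibody CPM (-1.53, adjusted p = 0.00731) and CD5 from 2753 to 1434 (-0.91, adjusted p = 0.0465). CD14, the co-receptor for bacterial lipopolysaccharide, rose from 34510 ± 10400 to 87160 ± 44320 (1.32, adjusted p = 0.0162) and CD80, a costimulatory ligand, from 7580 to 14490 (0.94, adjusted p = 0.0162). CD14 was lost without floxed isotype mouse 1 or 2 or floxed anti-PD-1 mouse 2 (adjusted p 0.0531 to 0.104). CD80 was lost without those and without floxed isotype mouse 4 (up to 0.106), and CD5 in 10 of 16 fits (0.0595 to 0.166). With the other hashtag rule, which moved a cluster of 2608 cells from monocytes to macrophages, 0 proteins passed and CD169 had adjusted p = 0.15. The protein count was 2 without floxed isotype mouse 1 and 1 without floxed isotype mouse 2 or floxed anti-PD-1 mouse 2, and 18 passed unadjusted p 0.05.

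With anti-PD-1, LysM-Cre monocytes had lower hypoxia, stress and exhaustion-list levels than floxed monocytes. All 12 hypoxia genes were lower (median -0.59, camera adjusted p = 3.98e-10, adjusted p = 0.0993 with an estimated correlation), 6 of them past the threshold when adjusted over the list alone, including Ndrg1 (183 ± 96.8 to 73.7 ± 14.9 CPM) and Ldha, lactate dehydrogenase (751 ± 116 to 561 ± 74.1 CPM). All 12 stress genes were lower (median -0.35, adjusted p = 1.17e-06, adjusted p = 0.0788 with an estimated correlation), 6 past the threshold over the list alone, including Atf3 and Jun. All 5 exhaustion genes were lower (median -0.73, adjusted p = 0.00248, adjusted p = 0.0605 with an estimated correlation). Without floxed anti-PD-1 mouse 1 the hypoxia median was -0.36 and the exhaustion median -0.29, and without floxed anti-PD-1 mouse 3 the exhaustion median was -0.42. Cdkn1a, a cell cycle inhibitor in the glucocorticoid list, fell when adjusted over the list alone (449 ± 115 to 287 ± 55.5 CPM). Cluster 14 held 24.3 ± 18.1% of monocytes in floxed and 11.1% in LysM-Cre mice with anti-PD-1. EdgeR called 0 genes (906 at unadjusted p 0.05, 36 by DESeq2), but 1 without floxed isotype mouse 1, 3 without floxed anti-PD-1 mouse 2 and 6 without LysM-Cre isotype mouse 4, and 0 proteins (10 at unadjusted p 0.05).

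Glucocorticoid-response genes, the list closest to the targeted receptor, were lower in the same comparison (15 of 23, median -0.28, camera adjusted p = 0.0139, adjusted p = 0.523 with an estimated correlation). The call was lost without floxed anti-PD-1 mouse 1 or 2 or LysM-Cre anti-PD-1 mouse 1, 2 or 3 (adjusted p 0.0553 to 0.169), and the median was -0.50 without LysM-Cre anti-PD-1 mouse 4. Outside myeloid cells the list passed by genotype upward in fibroblasts with both treatments (medians 0.35 and 0.25) and in CD8 T (0.28), NK (0.19) and regulatory T cells with isotype, and downward in CD4 T cells (-0.21). None of these passed with an estimated correlation, and without 1 mouse they were lost in 3 of 15 fits each in fibroblasts and CD8 T cells, 4 of 14 in NK and 5 of 7 in CD4 T cells (adjusted p up to 0.621). The list also passed upward for treatment in LysM-Cre macrophages (0.19, adjusted p = 0.44 with an estimated correlation, lost in 5 of 16 fits).

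The fitted response of monocytes to anti-PD-1 differed between genotypes in hypoxia and stress genes at camera's preset correlation only. All 12 hypoxia genes had a lower fitted response in LysM-Cre mice (median -0.50, camera adjusted p = 4.75e-10), as did 11 of 12 stress genes (-0.49, adjusted p = 9.82e-06). Both had adjusted p = 0.155 with an estimated correlation. Ndrg1 and Atf3 passed when adjusted over the list alone. All 27 interferon genes had a higher fitted response (0.38, adjusted p = 3.08e-07, adjusted p = 0.45 with an estimated correlation), though the median lay between 0.14 and 0.25 without floxed anti-PD-1 mouse 2, LysM-Cre isotype mouse 3 or 4 or LysM-Cre anti-PD-1 mouse 3, and was 0.74 and 0.71 without LysM-Cre isotype mouse 2 and floxed anti-PD-1 mouse 3. EdgeR and DESeq2 called 0 genes (441 at unadjusted p 0.05 in edgeR), and 0 proteins passed (6 at unadjusted p 0.05).

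With isotype, 1 of 12 lists passed between LysM-Cre and floxed monocytes. All 27 interferon genes were lower (median -0.42, camera adjusted p = 1.95e-09, adjusted p = 0.95 with an estimated correlation), which was lost without LysM-Cre isotype mouse 4 (-0.13, adjusted p = 0.28) and was -0.73 without LysM-Cre isotype mouse 2. Tgm2, transglutaminase 2, a glucocorticoid-response gene, fell when adjusted over the list alone (234 ± 71.2 to 139 ± 18.9 CPM), while the list did not pass (adjusted p = 0.460). EdgeR called 0 genes (328 at unadjusted p 0.05, 2 by DESeq2) and 0 proteins (3 at unadjusted p 0.05, 1 without floxed isotype mouse 4).

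In LysM-Cre monocytes, inflammatory genes were higher with anti-PD-1 (16 of 16, median 0.54, camera adjusted p = 3.67e-06, adjusted p = 0.363 with an estimated correlation), such as Il1b at 904 ± 132 and 1530 ± 287 CPM. Cell cycle genes were lower (12 of 12, -0.33, adjusted p = 0.000618, adjusted p = 0.172 with an estimated correlation), a call that Scrublet ended (adjusted p = 0.054). Without LysM-Cre anti-PD-1 mouse 4 the inflammatory median was 0.26, and the cell cycle median was -0.55 without LysM-Cre isotype mouse 2 and -0.53 without LysM-Cre anti-PD-1 mouse 1. Tgm2 rose when adjusted over the list alone (139 ± 18.9 to 233 ± 34.8 CPM), and Atf3, Zfp36, Fos and Jun of the stress list fell over the list alone. EdgeR and DESeq2 called 0 genes (425 at unadjusted p 0.05 in edgeR), and 0 proteins passed (7 at unadjusted p 0.05, 1 without LysM-Cre isotype mouse 3).

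CD8 T cells, in which the Lyz2 promoter is not known to be active, were compared for changes outside the targeted lineage. Dissociation-stress genes were lower in LysM-Cre than in floxed mice with both treatments. With anti-PD-1, 11 of 12 had lower fitted levels (median -0.69, camera adjusted p = 3.01e-16, adjusted p = 0.000686 with an estimated correlation), and 5 passed when adjusted over the list alone. Hspa1b, an inducible heat-shock chaperone, was at 540 ± 258 CPM in 3 floxed and 51.9 ± 28.8 CPM in 4 LysM-Cre mice, and Jun at 759 ± 105 and 429 ± 244 CPM. With isotype, 11 of 12 did (median -0.30, adjusted p = 7.82e-06, adjusted p = 0.0479 with an estimated correlation), and Hspa1a passed over the list alone (158 ± 112 to 22.2 ± 17.0 CPM). Reads of the near-identical Hspa1a and Hspa1b can be assigned to either copy. Without LysM-Cre anti-PD-1 mouse 4 the anti-PD-1 median was -1.21, and without floxed isotype mouse 3 the isotype median was -0.14. Interferon genes fell with anti-PD-1 in floxed mice (20 of 24, -0.63, adjusted p = 4.2e-13, 0.4 with an estimated correlation), with Bst2 past the threshold over the list alone (364 ± 72.7 to 188 ± 41.5 CPM), and in LysM-Cre mice (21 of 24, -0.51, adjusted p = 1.55e-06, 0.357 with an estimated correlation).

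In LysM-Cre mice, anti-PD-1 raised TIM3, an inhibitory receptor of activated T cells, on CD8 T cells from 1810 ± 225 to 3734 ± 689 antibody CPM (1.04, edgeR adjusted p = 0.0111), and Havcr2, its gene, passed when adjusted over the list alone (63.3 ± 24.4 to 134 ± 44.2 CPM). CD278, the costimulatory receptor ICOS, rose from 272 to 756 antibody CPM (adjusted p = 0.0203) and CD25, the interleukin-2 receptor alpha chain, from 1415 to 2318 (adjusted p = 0.0315). TIM3 was lost without LysM-Cre isotype mouse 1 (adjusted p = 0.0565) or LysM-Cre anti-PD-1 mouse 2 (0.0639), and CD278 and CD25 in 7 and 9 of 15 fits (0.052 to 0.147). The 3 proteins became 0 without LysM-Cre isotype mouse 1 or LysM-Cre anti-PD-1 mouse 2 and 1 without floxed isotype mouse 2, floxed anti-PD-1 mouse 1 or LysM-Cre isotype mouse 4, and also 1 without 2 barcodes of aggregated antibody, at resolution 2.0 or with 20% mitochondrial UMIs, and 0 with the other hashtag rule. Tissue-repair and macrophage genes, which doublets can carry over, were lower (8 of 11, -0.28, camera adjusted p = 0.00347, adjusted p = 0.35 with an estimated correlation). Apoe (860 ± 283 to 561 ± 141 CPM) was among the genes past the threshold over the list alone. The list's median lay between -0.18 and -0.15 without LysM-Cre anti-PD-1 mouse 4 or floxed anti-PD-1 mouse 1, 3 or 4. Stress genes were lower (10 of 12, -0.31, adjusted p = 0.00205, 0.222 with an estimated correlation), with -0.15 without LysM-Cre anti-PD-1 mouse 3, -0.19 without LysM-Cre isotype mouse 2 and -0.61 without LysM-Cre anti-PD-1 mouse 4.

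Single genes called in CD8 T cells were few. Slc17a6, a vesicular glutamate transporter (chromosome 7, 51621830 to 51671126, mm10), was at 81.0 ± 17.0 CPM in floxed isotype, 31.7 ± 11.6 in LysM-Cre isotype and 107 ± 29.6 CPM in LysM-Cre anti-PD-1 mice. It fell with genotype under isotype (-1.27, edgeR adjusted p = 0.0418) and rose with anti-PD-1 in LysM-Cre mice (1.64, adjusted p = 0.0114). Rgs10, a regulator of G-protein signalling, fell with anti-PD-1 in LysM-Cre mice (118 ± 21.4 to 52.0 CPM, -1.18, adjusted p = 0.0221). The genotype call was lost in 10 of 15 fits without 1 mouse (adjusted p 0.0587 to 0.38). The treatment call for Slc17a6 was lost without LysM-Cre isotype mouse 1 or LysM-Cre anti-PD-1 mouse 1 or 3 (0.0539 to 0.0936), and that for Rgs10 without LysM-Cre isotype mouse 1 or LysM-Cre anti-PD-1 mouse 1, 2 or 4 (0.11 to 0.152). The 2 genes became 4 without LysM-Cre isotype mouse 3. Counts by edgeR were 1 for genotype with isotype (169 at unadjusted p 0.05, DESeq2 0), 0 for genotype with anti-PD-1 (290, DESeq2 2), 0 for treatment in floxed (269), 2 for treatment in LysM-Cre (408, DESeq2 2) and 0 for the interaction (220). No surface protein passed in the other 4 comparisons (3, 6, 8 and 9 at unadjusted p 0.05). That count was 2 for genotype with isotype without LysM-Cre isotype mouse 3, 2 for genotype with anti-PD-1 without floxed anti-PD-1 mouse 3 and 3 without floxed anti-PD-1 mouse 4, and for treatment in floxed mice 1 and 3 without these.

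The fitted response of CD8 T cells to anti-PD-1 was higher in LysM-Cre mice for cell cycle genes (7 of 8, median 0.92, camera adjusted p = 0.000259, 0.1555 with an estimated correlation) and lower for stress genes (10 of 12, -0.35, adjusted p = 0.000259, 0.111 with an estimated correlation). The stress median was -0.55 without floxed isotype mouse 3, -0.21 without floxed anti-PD-1 mouse 3 and -0.86 without LysM-Cre anti-PD-1 mouse 4. Exhaustion genes were lower in LysM-Cre than in floxed mice with isotype (10 of 12, -0.27, adjusted p = 1.35e-05, 0.155 with an estimated correlation), lost without LysM-Cre isotype mouse 1 (-0.02, adjusted p = 0.0811).

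Regulatory T cells could be compared between genotypes with isotype only. Hspa1b (chromosome 17, 34956429 to 34959238, mm10) fell from 62.3 ± 16.6 to 6.39 ± 5.56 CPM (-3.96, edgeR adjusted p = 0.00134, lower in 4 of 4 LysM-Cre mice), the 1 gene of 5729 past the threshold (209 at unadjusted p 0.05, DESeq2 1). It was kept without each mouse, and with the other hashtag rule it had adjusted p = 0.052. The count was 5 without LysM-Cre isotype mouse 2 and 3 without LysM-Cre isotype mouse 4. Interferon genes were lower (23 of 26, median -0.25, camera adjusted p = 3.22e-07, adjusted p = 0.309 with an estimated correlation), with -0.45 without floxed isotype mouse 2, -0.63 without LysM-Cre isotype mouse 2, -0.12 without floxed isotype mouse 3 and -0.11 without LysM-Cre isotype mouse 4. Stress genes were lower (8 of 12, -0.29, adjusted p = 8.45e-05, adjusted p = 0.154 with an estimated correlation). Their median was -0.10 without floxed isotype mouse 3 or LysM-Cre isotype mouse 3, -0.17 without floxed isotype mouse 4 and -0.44 without LysM-Cre isotype mouse 4. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was higher when adjusted over the list alone (146.5 ± 47.6 to 325 ± 154 CPM). The glucocorticoid list (12 of 17 up, adjusted p = 0.0161, adjusted p = 0.208 with an estimated correlation) was kept only without floxed isotype mouse 3 or LysM-Cre isotype mouse 1 or 4 (otherwise 0.0583 to 0.138). No surface protein passed (1 at unadjusted p 0.05).

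In CD4 T cells with isotype, compared in 4 floxed and 3 LysM-Cre mice, Ly6c2, a surface antigen of effector and memory cells (chromosome 15, 75108161 to 75112066, mm10), rose from 149 ± 28.4 to 621 ± 305 CPM (2.12, edgeR adjusted p = 0.00247, higher in 3 of 3 LysM-Cre mice), the 1 gene of 3645 past the threshold (144 at unadjusted p 0.05, DESeq2 1). It was lost without floxed isotype mouse 3 (adjusted p = 0.124), and 11 genes passed without floxed isotype mouse 2 and 7 without LysM-Cre isotype mouse 2. Tissue-repair and macrophage genes, which doublets can carry over, were lower (8 of 10, median -0.81, camera adjusted p = 1.15e-06, adjusted p = 0.174 with an estimated correlation), a call that Scrublet ended. C1qb, a complement subunit of macrophages, was at 499.6 ± 152 and 213.5 ± 42.2 CPM and Apoe at 1769 ± 547 and 950 ± 190 CPM. The list's median was -0.37 without floxed isotype mouse 1. Stress genes were lower (9 of 11, -0.41, adjusted p = 2.06e-06, 0.174 with an estimated correlation), and -0.18, -0.69 and -0.20 without floxed isotype mouse 1 and LysM-Cre isotype mice 1 and 2. Interferon (23 of 23 up, 0.32, adjusted p = 0.000162, 0.3105 with an estimated correlation) and cytotoxic genes (5 of 5 up, 0.72, adjusted p = 0.000667, 0.174 with an estimated correlation) rested on LysM-Cre isotype mouse 2 (adjusted p = 0.797 and 0.32 without it). No surface protein passed (10 at unadjusted p 0.05, 1 without floxed isotype mouse 3).

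NK cells had lower stress genes in LysM-Cre than in floxed mice with anti-PD-1 (9 of 11, median -0.28, camera adjusted p = 0.000503, adjusted p = 0.333 with an estimated correlation), lost without floxed anti-PD-1 mouse 3 or LysM-Cre anti-PD-1 mouse 3 (adjusted p 0.057 to 0.0706) and -0.54 without LysM-Cre anti-PD-1 mouse 4. Hspa1b passed over the list alone with isotype (131 ± 79.5 to 27.1 ± 18.6 CPM). No gene passed by edgeR in 5 comparisons (158 at unadjusted p 0.05 for genotype with isotype, 320 with anti-PD-1, 241 for treatment in floxed, 406 in LysM-Cre mice, 223 for interaction). For genotype with isotype the count was 5 without LysM-Cre isotype mouse 2 and 1 without floxed isotype mouse 4. Without LysM-Cre anti-PD-1 mouse 1 it was 2 for genotype with anti-PD-1, 1 for treatment in LysM-Cre mice and 1 for the interaction. No surface protein passed (4, 1, 12, 4 and 1 at unadjusted p 0.05). Without LysM-Cre anti-PD-1 mouse 4 the protein count was 2 for genotype with anti-PD-1 and 1 for the interaction, and for treatment in floxed mice it was 4 without floxed isotype mouse 4 and 1 without floxed anti-PD-1 mouse 3.

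Neutrophils of LysM-Cre mice had higher inflammatory genes with anti-PD-1 than with isotype (14 of 14, median 0.69, camera adjusted p = 1.85e-10, adjusted p = 0.158 with an estimated correlation). Il1b, which encodes interleukin-1 beta, rose over the list alone from 11020 ± 1731 to 16530 ± 1600 CPM, Nlrp3, an inflammasome sensor, from 354.5 ± 124 to 691 ± 203 CPM, and Tnfaip3, a brake on NF-kappaB, from 149 ± 89.6 to 323 ± 65.7 CPM. Interferon genes were lower (15 of 19, -0.41, adjusted p = 2.34e-05, adjusted p = 0.378 with an estimated correlation), lost without LysM-Cre anti-PD-1 mouse 4 (adjusted p = 0.0884), and -0.22 without LysM-Cre isotype mouse 2 and -0.87 without LysM-Cre anti-PD-1 mouse 3. With isotype, LysM-Cre neutrophils had higher hypoxia genes than floxed ones (9 of 11, 0.35, adjusted p = 2.51e-05, adjusted p = 0.329 with an estimated correlation) and lower inflammatory genes (14 of 14, -0.48, adjusted p = 2.51e-05, adjusted p = 0.333 with an estimated correlation), the latter lost without floxed isotype mouse 1 (adjusted p = 0.17) or LysM-Cre isotype mouse 1 (0.129). EdgeR and DESeq2 called 0 genes for both comparisons (94 and 50 at unadjusted p 0.05 in edgeR), and without LysM-Cre isotype mouse 2, LysM-Cre anti-PD-1 mouse 1 or LysM-Cre isotype mouse 4 the treatment count was 1, 1 and 2. No surface protein passed (2 and 0 at unadjusted p 0.05).

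In cDC2 cells of floxed mice, tissue-repair and macrophage genes, which doublets can carry over, were lower with anti-PD-1 (12 of 13, median -0.82, camera adjusted p = 3.62e-06, 0.128 with an estimated correlation). C1qa fell from 366 ± 144 to 155 ± 75.0 CPM and Apoe from 912 ± 365 to 374 ± 71.8 CPM when adjusted over the list alone, whereas Fabp5, a fatty-acid carrier, rose from 67.5 ± 34.2 to 860 ± 946 CPM. With isotype, interferon genes were lower in LysM-Cre than in floxed cDC2 cells (26 of 27, -0.42, adjusted p = 9.3e-12, 0.616 with an estimated correlation), and -0.97 and -0.17 without LysM-Cre isotype mice 2 and 4. EdgeR called 0 genes for treatment in floxed mice (363 at unadjusted p 0.05, DESeq2 3) and 0 for genotype (153, DESeq2 1), and without LysM-Cre isotype mouse 2 both were 1. The treatment count was also 1 without floxed isotype mouse 3 or 4 or floxed anti-PD-1 mouse 1, and 2 without LysM-Cre isotype mouse 4 or floxed anti-PD-1 mouse 4. No surface protein passed (7 and 4 at unadjusted p 0.05).

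In floxed fibroblasts, CD9, a tetraspanin, and Podoplanin, a mucin of stromal cells, made up more of the antibody counts with anti-PD-1 than with isotype. CD9 rose from 18740 to 80790 antibody CPM (2.07, edgeR adjusted p = 0.00132) and Podoplanin from 64810 to 189000 antibody CPM (1.61, adjusted p = 0.00132), both kept without each mouse. CD44 (1.06) and CD137L (1.40) also rose, and the macrophage antigens CD68 (-2.16, 2893 to 580 antibody CPM) and CD169 (-3.09, 1754 to 160) fell, at adjusted p between 0.0196 and 0.0243. Same-hashtag doublets, expected less often with anti-PD-1, may alone shift these antibody shares (not tested). The 6 proteins (19 at unadjusted p 0.05) became 2 without floxed anti-PD-1 mouse 1 or 4 or floxed isotype mouse 4. MHC class II genes (7 of 7, median -1.82, camera adjusted p = 1.75e-05, 0.458 with an estimated correlation) and tissue-repair and macrophage genes (15 of 18, -1.10, adjusted p = 2.47e-05, 0.458 with an estimated correlation) were lower along with CD68 and CD169. Between genotypes with anti-PD-1 both were higher in LysM-Cre mice, MHC class II in 7 of 7 (1.91, adjusted p = 7.94e-08, 0.255 with an estimated correlation) and macrophage genes in 15 of 18 (1.61, adjusted p = 1.13e-15, 0.053 with an estimated correlation), with C1qa (64.3 ± 26.3 to 302 ± 141 CPM) among 8 past the threshold over the list alone.

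Cxcl12, a chemokine of stromal cells (chromosome 6, 117168535 to 117181368, mm10), fell in floxed fibroblasts with anti-PD-1 from 151 ± 47.8 to 36.9 ± 11.1 CPM (-1.97, edgeR adjusted p = 0.0495), with Igsf3 lower and Slc5a3 and Qpct higher among 7 genes at that adjusted p (927 at unadjusted p 0.05, DESeq2 31). Each was lost in 13 to 15 of the 15 fits without 1 mouse. The count was 4 without floxed anti-PD-1 mouse 1, 2 without floxed isotype mouse 3, 5 without LysM-Cre anti-PD-1 mouse 4 and 0 in the other 12 fits. Over both genotypes 60 genes passed for treatment, 32 of them higher. EdgeR called 0 genes for genotype with isotype (270 at unadjusted p 0.05, DESeq2 0), genotype with anti-PD-1 (643, DESeq2 12), treatment in LysM-Cre mice (830, DESeq2 16) and the interaction (363, DESeq2 0). These were 1 for genotype with anti-PD-1 without floxed isotype mouse 2 or LysM-Cre isotype mouse 2, and for treatment in LysM-Cre mice 1 without LysM-Cre isotype mouse 2 and 5 without LysM-Cre anti-PD-1 mouse 4. No protein passed in them (4, 9, 9 and 8 at unadjusted p 0.05).

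Fibroblasts of LysM-Cre mice had lower cell cycle genes with anti-PD-1 than with isotype (13 of 14, median -0.78, camera adjusted p = 3.48e-06, adjusted p = 0.793 with an estimated correlation). With isotype they had lower interferon genes than floxed ones (23 of 27, -0.41, adjusted p = 7.6e-08, adjusted p from 0.353 to 0.595 with an estimated correlation for the lists of this comparison), which were -0.98 without LysM-Cre isotype mouse 2 and -0.17 without LysM-Cre isotype mouse 4. In 2 cases the median of a list and its test differed in sign. Stress genes between genotypes with anti-PD-1 had a median of 0.01 and a mean of -0.31 (6 of 12 down, adjusted p = 0.035), and cytotoxic genes with anti-PD-1 in floxed mice a median of 0.12 and a mean of -0.88 (2 of 5 down, adjusted p = 0.0472), through Hspa1a (-2.18) and Ccl5 (-2.67). The first call was lost in 3 and the second in 12 of 15 fits without 1 mouse (adjusted p up to 0.923 and 0.868), and neither passed with an estimated correlation.

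Over all 9 classes, 115 of 347 list tests passed with camera's preset correlation, 2 with an estimated correlation, both the stress list in CD8 T cells between genotypes, and 5 with fry. By list, the glucocorticoid response passed in 10 of 31 tests, MHC class II in 13, interferon in 19, inflammatory cytokines in 10, tissue-repair in 8, hypoxia in 10 and stress in 15 of 31. Exhaustion passed in 5, cytotoxic effector in 8 and naive and memory T in 2 of 29 tests, cell cycle in 14 of 28 and fibroblast markers in 1 of 15. Melanoma, endothelial and red cell markers had too few tested members for a set test. Over all cells of a mouse, melanoma markers summed to between 9.73 and 27.3 CPM, endothelial markers to between 14.9 and 45.6, fibroblast markers to between 307 and 1580 and red cell genes to between 20.5 and 4371 CPM.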

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

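The tests of free RNA, of same-mouse doublets by correlation, of 1 mouse and a fixed Lyz2 share for Lyz1, and the merged macrophage and monocyte class, were chosen only after the result was seen.

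A mouse lay far from the other 3 in 13 of 188 groups of 4, and chance gives about 1 in 20 groups. In LysM-Cre anti-PD-1 mice the highest was 5.543% for CD4 T cells (nearest 1.51%), 33.79% for neutrophils (8.314%) and 8.545% for regulatory T cells (2.825%). In LysM-Cre isotype mice it was 91.21 CPM for Nr3c1 in fibroblasts (82.18) and 360.2 CPM for Lyz1 in macrophages and monocytes (46.49). In mean log2 CPM of lists, LysM-Cre anti-PD-1 macrophages had a lowest mouse at 2.737 for cytotoxic (3.472) and 5.084 for interferon genes (6.216) and a highest at 6.382 for glucocorticoid response (5.707). Monocytes of this condition had a lowest at 2.667 for cell cycle (2.87) and 3.493 for cytotoxic (3.915) and a highest at 7.693 for tissue-repair genes (7.401). Floxed isotype mice had a lowest at 5.482 for interferon genes in macrophages (6.51) and at 3.818 for cytotoxic genes in monocytes (4.324).

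The interaction of genotype and treatment passed in camera at the preset correlation for 14 lists and with an estimated correlation for 0. The median log2 differences were 0.92 for cell cycle and -0.35 for stress in CD8 T cells, 0.84 for interferon, 1.03 for tissue-repair, -0.24 for hypoxia and -0.18 for stress in fibroblasts, 0.69 for MHC class II and 1.26 for interferon in macrophages, and 0.98 for MHC class II in NK cells. In monocytes they were -0.24 for glucocorticoid response, 0.38 for interferon, -0.46 for cell cycle, -0.50 for hypoxia and -0.49 for stress. Without 1 mouse the call was lost in 9 of 14 fits for MHC class II in NK cells (adjusted p up to 0.324), 7 of 16 for cell cycle (0.166) and 1 of 16 for glucocorticoid response in monocytes (0.0518, medians -0.50 to -0.0813), and 6 of 15 for hypoxia (0.317, -0.50 to -0.11) and 3 of 15 for stress in fibroblasts (0.337), where Scrublet gave 0.41. Clusters without a name held 784, 376, 317, 73, 46 and 21 cells.

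In macrophages 12 T and NK cell markers were at 77.5 ± 64.8 CPM in floxed isotype and 10.4 ± 5.96 CPM in floxed anti-PD-1 mice, and at 26.4 ± 6.68 and 9.45 ± 5.85 CPM in LysM-Cre mice (exact permutation p = 0.0286 in each genotype, the smallest 4 against 4 can give), against 5059 CPM in CD8 T cells. Free RNA, shared by all mice of a pool, was argued against by ratios of the highest to the lowest mouse of 74.4 in pool E5 and 8.54 in E6. Doublets of 2 cells of a mouse are a candidate explanation, since the level followed the mouse's T and NK cells as a share of the pool (rho = 0.818, permutation p = 0.00023; r = 0.744, p = 2e-05, 0.807 without the 2 farthest mice). Within pools rho was 0.857 in E5 (exact p = 0.0107; r = 0.717, 0.569 without the 2 farthest) and 0.786 in E6 (exact p = 0.0279; r = 0.981 and 0.872). Removing Scrublet calls, which takes out doublets only in part, left it open (median log2 change -1.26, 9 of 12 markers lower, against -2.61 and 12 of 12). Any change of these genes with treatment also leaves it open and was not tested apart.

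Lyz1, a neighbour and near-copy of the Cre-carrying Lyz2, was at 6.08 ± 2.51 CPM in macrophages and monocytes of 8 floxed and 147 ± 149 CPM of 8 LysM-Cre mice (8 of 8 above every floxed mouse, exact permutation p = 0.000155, the smallest possible; edgeR adjusted p = 0.108). The tables argue against 1 mouse alone (lowest LysM-Cre over highest floxed 2.24) and a fixed share of Lyz2 reads counted as Lyz1 (the same for Lyz1 per Lyz2, 1.57). Reads shared with Lyz2 stay open over 8 LysM-Cre mice (rho = 0.119, exact permutation p = 0.793; r = 0.0625, p = 0.875, 0.677 without the 2 farthest), and pools of 4 are too few. A strain segment at the insertion also stays open, with 12.5% of 32 genes within 5 Mb under p 0.05 against 5.4% of all genes. So does an effect of genotype, which was not tested apart.

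Interferon genes in floxed macrophages fell with anti-PD-1 from a mean log2 CPM of 6.32 ± 0.56 to 4.77 ± 0.87. A shift between clusters was argued against as the whole cause by -0.92 within cluster 3 (25 of 26 genes lower), with -1.61 in cluster 13 (7 mice), while cluster 12 could not be fitted. So was 1 mouse alone, by -1.01 without floxed anti-PD-1 mouse 2. RNA content stays open over 8 floxed mice (rho = -0.524, exact permutation p = 0.197; r = -0.594, p = 0.118, -0.569 without the 2 farthest), with pools of 4 too few. Chance was not excluded, as 3 of 35 splits had a camera p as small (3.42e-25, smallest other 6.61e-49), and an effect of treatment stays open.

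By other splits of the same mice, uncorrected for the number of counts tested, chance was excluded (1 of 35 splits as large) for treatment in floxed mice in macrophages (2 genes, highest other 1), monocytes (3 genes against 1, 4 proteins against 2) and fibroblasts (7 genes against 2, 6 proteins against 3), and for treatment in LysM-Cre CD8 T cells (3 proteins against 0, 7 lists against 5). For genotype with anti-PD-1 in NK cells, 10 splits are too few (0 genes against 5, 0 proteins against 0, 1 list against 4). For the other counts above 0, chance could not be excluded even without such a correction. Where the real count is 0, every split is as large by construction (35, or 100 for an interaction), which decides nothing. Where edgeR called 0 genes the highest others were 1 to 5, except 9 and 50 in NK cells for genotype with isotype and treatment in LysM-Cre mice and 20 in macrophages for the interaction, and where it called 0 proteins they were 0 to 9. Of 35 splits, 6 were as large for the CD8 T gene by genotype (highest 4), 5 for the 2 CD8 T genes by treatment (11), 14 for the regulatory T gene (37) and 21 for the CD4 T gene (43). The 50, 43, 37, 20 and 11 genes may point to a structure of the samples other than the conditions (the pool alone was tried). The protein by treatment in floxed macrophages had a highest other of 2 (4 splits as large). Lists follow in the order genotype with isotype, genotype with anti-PD-1, treatment in floxed, treatment in LysM-Cre mice and interaction, without those already named. Macrophages had 3, 3, 3, 4 and 2 against 9, 7, 7, 9 and 8 (27, 25, 23, 20 and 89 splits as large), monocytes 1, 6, 6, 4 and 5 against 7, 7, 8, 8 and 7 (33, 5, 7, 16 and 17). CD8 T cells had 5, 3, 2 and 2 against 8, 6, 8 and 8 (11, 18, 29 and 86). Fibroblasts had 7, 5, 7, 4 and 4 against 10, 9, 9, 8 and 8 (12, 19, 12, 27 and 83). NK cells had 6, 4, 1 and 1 against 8, 7, 5 and 8 (8, 15, 34 and 92), neutrophils 2 and 2 against 5 and 7 (25 and 26), regulatory T cells 4 against 7 (17), CD4 T cells 8 against 9 (3) and cDC2 2 and 1 against 6 and 8 (25 and 34). The split that follows the pool gave 28 genes, 2 proteins and 5 lists in regulatory T cells and 22 genes and 1 protein in CD4 T cells. It also gave at least as many as the real split for proteins by genotype in NK cells and fibroblasts with isotype and CD8 T cells and fibroblasts with anti-PD-1. For lists it did so by genotype in macrophages, monocytes, fibroblasts, neutrophils and cDC2 with isotype and macrophages, CD8 T cells and fibroblasts with anti-PD-1, and by treatment in floxed CD8 T cells and cDC2 and LysM-Cre monocytes and neutrophils. The reported fits hold the pool as a term.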

How the results depend on the processing

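The antibody fits without 2 barcodes of aggregated antibody were the setting here chosen only after the result was seen. No paired analysis was possible because the hashtag table does not number mice within conditions, so the planned replicate block was not run. Comparisons between classes and by surface protein were planned only for hashtags without a stated condition and were not run. With at least 50 cells per mouse, 18 of the 31 comparisons of genes could not be fitted. Fibroblasts could not be compared for treatment in floxed mice, genotype with anti-PD-1 or the interaction with the other hashtag rule, nor cDC2 for treatment in floxed mice with 20% mitochondrial UMIs or Scrublet. Depth limits the genes tested, with 2140 in neutrophils (at least 51152 UMIs per mouse) and 10116 in fibroblasts (at least 452861).

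No class share passed in 36 alternative results or 80 without 1 mouse, which the smallest possible p all but precluded. Median cells per mouse moved by less than the spread between mice with the other hashtag rule or mitochondrial limit. Cells in named classes were 99.45% at resolution 0.5, 92.08% at 2.0 and 90.86% after Scrublet. Among alternatives other than leaving out a mouse, 180 counts of genes stayed within 1.5 times the value in the report and 76 moved, with 148 and 77 for lists and 264 and 23 for proteins. Single lists kept the direction and call of their test in 614 cases, lost the call in 214 and reversed in 13. Named genes and proteins, including Nr3c1 without a call, stayed on their side of the threshold in 223 cases, lost a call in 77 and gained one in 3. Without 1 mouse these were 323, 212 and 1. The cause was not tested for any move below, except that fits without 1 mouse or with 50 cells have fewer mice.

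Values by class follow the order genotype with isotype, genotype with anti-PD-1, treatment in floxed, treatment in LysM-Cre mice and interaction. They are for neutrophils genotype with isotype and treatment in LysM-Cre mice, for cDC2 genotype with isotype and treatment in floxed mice, and for regulatory and CD4 T cells genotype with isotype. Counts of genes past adjusted p 0.05 start from those of edgeR in the report. DESeq2 called 0, 22, 117, 3 and 0 in macrophages, 2, 36, 145, 0 and 0 in monocytes, 0, 2, 0, 2 and 0 in CD8 T cells, 0, 12, 31, 16 and 0 in fibroblasts, 0, 0, 2, 0 and 2 in NK cells, and 1 and 3 in cDC2. Without a filter on low counts edgeR called 103, 314, 415, 182 and 155 in macrophages, 72, 228, 521, 144 and 84 in monocytes, 5, 13, 18, 24 and 9 in CD8 T cells. It called 152, 322, 505, 381 and 140 in fibroblasts, 1, 2, 4, 1 and 1 in NK cells, 1 and 3 in neutrophils, 8 in regulatory T cells, 13 in CD4 T cells, and 1 and 30 in cDC2.

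For treatment in floxed macrophages, genes were 9 at resolution 0.5, 12 at resolution 2.0, 8 after Scrublet, 24 with 20% mitochondrial UMIs and 1 with the other hashtag rule. In floxed monocytes they were 6 at resolution 2.0 and 1 with 50 cells, where genotype with anti-PD-1 gave 3. In floxed fibroblasts they were 0 after Scrublet, 3 with 20% mitochondrial UMIs and 2 without the pool term. The CD8 T gene by genotype with isotype was lost (0) at both resolutions, with 50 cells, 20% mitochondrial UMIs and the other hashtag rule. The 2 CD8 T genes by treatment in LysM-Cre mice became 1 at resolution 0.5 and 0 at resolution 2.0, with 20% mitochondrial UMIs and with the other hashtag rule. Genotype with anti-PD-1 gave 1 in CD8 T cells at resolution 0.5 and with the other hashtag rule. Regulatory T cells gave 2 at resolution 2.0, after Scrublet and with the other hashtag rule, and 3 with 20% mitochondrial UMIs, where CD4 T cells gave 0. Neutrophils gave 6 by treatment with the other hashtag rule, and cDC2 gave 1 by treatment at resolution 0.5 and without the pool term.

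Of the counts of surface proteins, all 31 stayed within 1.5 times with centred log ratios. In floxed macrophages they were 4 at resolution 0.5, 5 at resolution 2.0, 2 after Scrublet, 6 with 20% mitochondrial UMIs, 4 with the other hashtag rule (1 by genotype with anti-PD-1) and 0 with 50 cells. In floxed monocytes they were 1 with 20% mitochondrial UMIs or 50 cells, 0 with the other hashtag rule and 2 without isotype control antibodies. In LysM-Cre CD8 T cells they were 5 at resolution 0.5 (1 each by genotype with anti-PD-1 and interaction), 1 at resolution 2.0, with 20% mitochondrial UMIs and without aggregate barcodes, and 0 with the other hashtag rule. Scrublet gave 0, 2, 22, 1 and 2 in fibroblasts. The other hashtag rule gave 1 in cDC2 of floxed mice.

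Counts of gene lists past adjusted p 0.05 start from those compared with other splits of the mice. With an estimated correlation camera gave 0 in 29 of the 31 comparisons and 1 in CD8 T cells for genotype with either treatment. Resolution 0.5 gave 5, 4, 5, 5 and 3 in macrophages and 7, 2, 5, 6 and 4 in CD8 T cells. Resolution 2.0 gave 5, 5, 5, 3 and 4 in macrophages, 2 in floxed NK cells, and 1 and 4 in cDC2. Scrublet gave 4 in LysM-Cre CD8 T cells, 2 in LysM-Cre fibroblasts, 3, 1, 1, 3 and 0 in NK cells, and 5 in cDC2 by genotype. The 20% limit gave 5, 4, 5, 4 and 5 in macrophages, 8, 1, 3, 7 and 4 in CD8 T cells, 6, 1, 0, 1 and 0 in NK cells, and 5 in cDC2 by genotype. The other hashtag rule gave 2, 4, 6, 3 and 4 in macrophages, 2 in LysM-Cre monocytes, 8, 4, 3, 4 and 1 in CD8 T cells, 4, 4, 1, 3 and 1 in NK cells, 2 and 7 in neutrophils, and 1 and 4 in cDC2. With 50 cells there were 4, 6, 6, 3 and 3 in macrophages and 3 in NK cells by genotype with isotype. Without the pool term there were 2 in LysM-Cre macrophages, 2 in LysM-Cre fibroblasts, 0 in floxed NK cells and 4 in floxed cDC2.

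Lists whose test reversed direction had medians, for the cell cycle, of 0.0686 in CD8 T cells by genotype with anti-PD-1 and 0.19 by treatment in floxed mice at resolution 0.5, -0.17 for the former with the other hashtag rule, and -0.0706 in cDC2 by genotype at resolution 2.0. Scrublet reversed stress genes in fibroblasts (0.23 by genotype with anti-PD-1, 0.41 for the interaction, 0.19 for treatment in LysM-Cre mice) and MHC class II genes (0.75 in LysM-Cre fibroblasts, 0.0296 in NK cells by genotype with isotype and 0.0671 by treatment in floxed mice). The other hashtag rule gave 0.0873 for inflammatory and -0.0792 for MHC class II genes in NK cells by genotype with isotype. Interferon genes in floxed monocytes were -0.0045 with 50 cells.

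Without 1 mouse at a time, genes ranged over 0, 0 to 4, 0 to 31, 0 to 1 and 0 in macrophages, 0, 0 to 6, 0 to 28, 0 and 0 in monocytes, 0 to 1, 0, 0, 0 to 4 and 0 in CD8 T cells. They were 0, 0 to 1, 0 to 5, 0 to 5 and 0 in fibroblasts, 0 to 5, 0 to 2, 0, 0 to 1 and 0 to 1 in NK cells, 0 and 0 to 2 in neutrophils, 1 to 5 in regulatory T cells, 0 to 11 in CD4 T cells, and 0 to 1 and 0 to 2 in cDC2. Proteins ranged over 0, 0, 0 to 4, 0 to 2 and 0 in macrophages, 0 to 1, 0, 1 to 6, 0 to 1 and 0 in monocytes, 0 to 2, 0 to 3, 0 to 3, 0 to 3 and 0 in CD8 T cells, 0 to 1, 0 to 1, 2 to 8, 0 and 0 to 1 in fibroblasts, 0, 0 to 2, 0 to 4, 0 and 0 to 1 in NK cells, and 0 to 1 in CD4 T cells. Lists ranged over 1 to 4, 3 to 4, 3 to 5, 2 to 5 and 1 to 5 in macrophages, 0 to 3, 3 to 7, 5 to 7, 2 to 7 and 3 to 7 in monocytes, 2 to 7, 2 to 4, 1 to 5, 3 to 7 and 2 to 4 in CD8 T cells. They were 3 to 11, 3 to 6, 5 to 8, 1 to 6 and 3 to 6 in fibroblasts, 1 to 7, 0 to 2, 0 to 5, 0 to 4 and 0 to 2 in NK cells, 1 to 3 and 2 to 3 in neutrophils, 4 to 9 in CD4 T cells, and 1 to 6 and 1 to 7 in cDC2. Medians of lists whose test reversed without 1 mouse ranged from -0.67 to -0.0902 (cell cycle, floxed fibroblasts), -0.35 to -0.0057 (cell cycle, macrophages by genotype with isotype), -0.21 to 0.15 (stress, fibroblasts by genotype with anti-PD-1), -0.45 to 1.24 (inflammatory, fibroblasts by genotype with isotype), -0.10 to 0.46 (interferon, CD4 T cells), -0.18 to 0.43 (interferon, LysM-Cre monocytes) and -0.62 to -0.0045 (interferon, floxed monocytes). Other medians crossed 0 without a reversed test, as for interferon in NK cells (-0.70 to 0.0745) and exhaustion in fibroblasts (-0.21 to 0.91) by genotype with isotype.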

Other observations

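Relations here were chosen only after the result was seen. Cd163, a scavenger receptor, followed its surface protein over the macrophages of 16 mice (r = 0.908, permutation p = 1e-05, the smallest they can give; rho = 0.803, p = 3e-04; r = 0.833 without the 2 farthest mice). It held in pool E6 (r = 0.938, 0.884 without the 2 farthest), while in E5 it rested on 2 mice (0.867 and -0.218). Over 8 floxed mice r was 0.959, and over 8 LysM-Cre mice 0.532 (exact permutation p = 0.179).

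Hspa1a and Hspa1b were lower in LysM-Cre mice in all 26 fits by class and treatment (median -1.72, from -0.17 to -3.96), of which 1 passed over all genes and 8 adjusted over the list alone. Classes of a mouse are not independent. Per mouse over all cells, their sum was 191 ± 103 CPM in floxed and 95.7 ± 46.7 CPM in LysM-Cre mice with isotype (exact permutation p = 0.171), and 305.0 ± 195 and 75.55 ± 21.1 CPM with anti-PD-1 (exact p = 0.143). In pool E6 all 4 LysM-Cre mice lay below every floxed mouse (exact p = 0.0286), and in E5 1 of 4 (exact p = 0.286).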
